A study of Mus musculus with 2 samples.

How the data were processed

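Poly-A selected, directional RNA libraries were prepared from MIN6 cells and sequenced as 42 bp paired-end reads, per the labels' protocols. The titles assign 1 library to C2cd4a-GFP and 1 to control-GFP, and the treatment text of both labels names the C2cd4a-GFP construct, so the groups rest on the titles and the characteristics. STAR 2.5.2b, featureCounts, Subread 1.5.2 and DESeq2 1.14.1 and the build mm10 are named in the submitters' processing notes, without their roles. The deposited counts are whole numbers per gene, with exon coordinates, strand and summed exon length beside them per the file headers. Whether counting used strand is not given in the sources used here, so overlapping and antisense genes cannot be told apart with certainty.

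The authors' p-values and adjusted p-values stand beside a log2 fold change of C2cd4a-GFP over control-GFP. They are taken to come from DESeq2, which the title of the deposited sheet and the processing notes name. A further table deposited by the authors holds 1 normalized value (treated as a score) per gene and condition, rounded to whole numbers. For 100% of the 26328 genes joined by a unique symbol, the log2 ratio of those values, with 1 added to each, gives the authors' log2 fold change within 0.005. These normalized values are not a rescaling of the raw counts. Among genes with at least 5000 counts, normalized over raw ran from 0.874 to 1.27 (5th to 95th percentile) in the C2cd4a-GFP library and from 0.93 to 1.09 in the control library. How many libraries stand behind the authors' normalized values and p-values is not given in the sources used here, and they are used only as the authors' values. The authors' normalized values draw on more than the deposited raw counts. Aldh1a3, for instance, had 0 counts in both libraries but a normalized value of 1 for C2cd4a-GFP. No value of theirs counts as independent of the raw counts.

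Raw counts of 27179 gene rows were analysed. Dates had replaced 27 symbols, which were looked up by gene ID in a RefSeq table of assembly GRCm38.p6, and 847 rows without a symbol were kept under their gene ID. Counts were scaled with TMM factors from edgeR 4.0.16 in R 4.3.3 (1.015 and 0.985), and expressed as CPM. The ratio of each gene was C2cd4a-GFP over control-GFP, with an exact Clopper-Pearson 95% interval conditional on the sum of its counts. No molecular identifiers are named in the labels, so intervals and floors cover counting error only, and a count of 0 was read as up to 3 counts. With 1 library per group no replicate test could be fitted, and no p-value across genes was computed. Genes with a mean of at least 1 CPM were called higher or lower by size, at a ratio of at least 1.5 either way with an interval excluding equal levels. Such a call compares these libraries and not the conditions.

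The words rose and fell were kept for genes with an adjusted p under 0.05 in the authors' deposited table. For 29 gene lists the authors' p-values were also adjusted by the Benjamini-Hochberg method over the list alone. Each list's median ratio was placed among 10000 random lists of the same size, drawn from 20 bins of mean expression without the list's own genes, and a list stood apart outside their central 95%. This percentile describes these libraries. The groups, the gene lists, the size rule and all alternatives except those said below to be added were fixed before the data were examined.

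Named genes were C2cd4a and its paralogs, and the 10 higher and 10 lower genes of at least 5 CPM whose interval bound lay farthest from equality, leaving out unnamed gene models. To these were added up to 4 members of each list by the same ranking (the 2 most abundant where no member met the size rule) and a fixed set of beta-cell and metabolic genes. Other genes named from the authors' calls, and the added sets of HIF and ERK targets, were chosen after their values or those of related genes were seen. Some genes that the rule names are not reported here.

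The procedure was tested on Poisson counts simulated around the pooled mean of the 2 libraries, at their real totals. Such counts vary by counting error alone, as the intervals assume. The simulation therefore checks the calculation and gives no rate of false calls between cultures. With no change, 30 of 12737 unchanged genes met the size rule and 95.6% of intervals held the true value. With 200 genes changed, 99% of the genes changed 2-fold and 52% of those changed 1.5-fold were recovered, 100 genes each. Of 40 random lists of 25 genes, 3 stood apart with no shift and 40 with a shift of 0.3 on the log2 scale.

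Alternatives covered the scaling (DESeq2 1.42.0 size factors, total counts, upper quartile), thinning to the same total, a prior count of 2, the filter, the size rule, the bins and the mean in place of the median. After seeing the data, a correction for exon length and GC content was added, in which lowess curves with a span of 0.3 were subtracted from the log2 ratio. GC content came from the longest GENCODE M21 transcript (GRCm38) of the same symbol and was found for 12359 genes (96.9% of those tested). Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.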

Results

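Gene expression was measured by RNA sequencing in MIN6 cells, a mouse insulinoma line that secretes insulin and is used as a model of the pancreatic beta cell. The cells had been infected with adenovirus at a multiplicity of infection of 100, and RNA was taken 72 to 96 h later. The library labelled C2cd4a-GFP comes from cells expressing C2cd4a fused to green fluorescent protein, and the library labelled control-GFP from cells expressing the control construct. There was 1 library per condition, with 30164106 counts in the C2cd4a-GFP library and 31039999 in the control library, so the difference between them has no replicate check. Intervals given with ratios are 95% exact counting intervals (log2 scale) and cover counting error only. The series asks about the role of C2cd4a, a gene near a human diabetes risk locus, in beta cells, and the comparison addresses which transcripts differ when it is overexpressed.

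C2cd4a was the most strongly raised transcript of the pair. Its gene (gene ID 244911, mm10 chromosome 9, 67830532 to 67832330) had 49238 counts in the C2cd4a-GFP library and 133 in the control library. These correspond to 1608 and 4.35 CPM (scaled counts relative to library size), a 370-fold difference and a log2 ratio of 8.53 (8.29 to 8.79). The authors' deposited table gives a log2 fold change of 8.86 for C2cd4a. These counts do not separate transcripts of the introduced construct from those of the cells' own C2cd4a. Its paralogs went the other way or were hardly seen. C2cd4b (gene ID 75697), which lies on the same chromosome at 67759437 to 67760933, had 1400 against 2102 counts and a log2 ratio of -0.59 (-0.69 to -0.49), and C2cd4c had -0.25 (-0.36 to -0.14). Neither passed in the authors' deposited table, where C2cd4b had a log2 fold change of -0.34 (DESeq2 adjusted p = 0.176) and C2cd4c of -0.16 (adjusted p = 0.404). C2cd4d had 0 counts in both libraries, which allows up to 0.098 CPM in each.

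Outside C2cd4a itself, the C2cd4a-GFP library held more prodynorphin, stanniocalcin and ERK-responsive transcripts and far less lactate dehydrogenase, lactate transporter and inducible heat shock transcript. Pdyn, the precursor of dynorphin peptides, had 3751 counts against 894, a log2 ratio of 2.07 (1.96 to 2.17). Stc2, a secreted glycoprotein, was at 1.69 (1.54 to 1.84). The transcription factor gene Etv5 was at 1.60 (1.42 to 1.78) and Dusp6, a phosphatase that dephosphorylates ERK, at 1.66 (1.41 to 1.91). At the other end, Ldha, which converts pyruvate to lactate, had 147 counts against 2521, a 17.2-fold lower level and a log2 ratio of -4.10 (-4.35 to -3.86).

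Among 12759 genes with a mean of at least 1 CPM, 540 were at least 1.5-fold higher and 540 at least 1.5-fold lower in the C2cd4a-GFP library, with a counting interval that excluded equal levels. Genes of at least 5 CPM were ranked by the interval bound nearest to equality, not by the ratio itself. Further genes named by this ranking as higher were Dyrk4 (log2 ratio 1.80), Adam8 (1.63), Kitl (1.37), Pde10a (1.27) and Fam129a (1.23). Those named as lower, besides Ldha, were Hspa1a (-4.25), Hspa1b (-2.97), Slc16a3 (-2.22), Npas4 (-1.84), Slc2a1 (-1.79), Bnip3 (-1.69), Rem2 (-1.64), Narf (-1.63) and Trpm5 (-1.25). Hspa1a and Hspa1b are near-identical copies on chromosome 17, so how their reads divide is uncertain. In the authors' deposited table all of these genes passed an adjusted p of 0.05 in the same direction, with log2 fold changes from 0.93 for Pde10a to 2.03 for Pdyn and from -3.97 for Hspa1a to -1.20 for Trpm5. Of 14619 genes with an adjusted p in the authors' deposited table, 1023 rose (7.0%) and 962 fell (6.58%). Of the genes that met the size rule, 391 of the higher and 350 of the lower also passed in the authors' deposited table in the same direction. All 1985 genes that passed in the authors' deposited table had the same direction in the pair. The ratios of the 2 libraries and the authors' deposited table had a Pearson r of 0.918 across the 12759 genes, which are not independent replicates, and the authors' values may include these libraries. Scaling by total counts gave 682 higher and 453 lower genes, and removing a trend of the ratio with exon length and GC content gave 406 and 350.

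**Figure D1:**
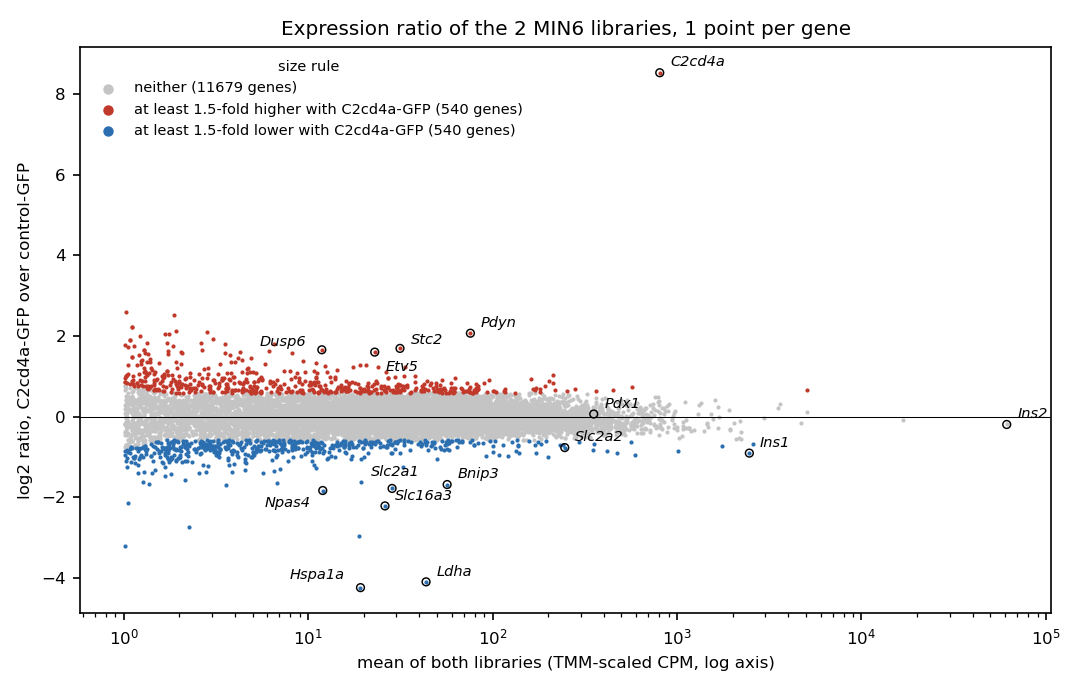
Each point is 1 of 12759 genes, with the mean TMM-scaled CPM of both libraries on a log axis and the log2 ratio of C2cd4a-GFP over control-GFP on the vertical axis. Red and blue points are the 540 higher and 540 lower genes by the size rule, and C2cd4a lies alone at 8.53 while Ldha and Hspa1a lie near -4.

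Transcripts of glycolysis and of the hypoxia response were lower as groups in the C2cd4a-GFP library. Of 25 measured glycolysis genes, 22 had a ratio below 1, and the median log2 ratio was -0.58, below all of 10000 random lists matched on expression (central 95%: -0.16 to 0.10). The authors' deposited table has 18 of the 25 falling and 1 rising at an adjusted p under 0.05 over all genes, and 19 falling and 1 rising when adjusted over the list alone. Lower members lay at several points of the pathway. They ran from the glucose transporters Slc2a1 (-1.79, -1.95 to -1.62) and Slc2a2 (-0.77, -0.82 to -0.72) through Pfkl (-1.01), Aldoa (-0.95) and Eno1 (-0.90) to the lactate exporter Slc16a3 (-2.22, -2.41 to -2.03). The other 6 of the 25 neither rose nor fell in the authors' deposited table, with Gapdh (-0.24) and Pklr (-0.30) among them. Of 3 members with a ratio above 1, only Hk1, a high-affinity hexokinase that beta cells normally keep low, met the size rule, at 0.60 (0.43 to 0.78). The authors' deposited table has Hk1 rising by a log2 fold change of 0.82 (adjusted p = 1.81e-06). Slc16a1, another monocarboxylate transporter, stayed near equality at 0.05 (-0.09 to 0.18). Krt8, a marker of acinar and ductal cells, was lower with this group, at 2983 counts against 5539 (-0.90, -0.96 to -0.83).

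The hypoxia response list, which shares 4 measured genes with glycolysis, had a median of -0.47 over 20 measured genes, again below all random lists (-0.16 to 0.14). Of these genes 12 fell and 0 rose in the authors' deposited table, and 14 fell and 0 rose when adjusted over the list alone. Bnip3, a mitochondrial protein of mitophagy, was at -1.69 (-1.80 to -1.57), Ankrd37 at -1.22 and the collagen prolyl hydroxylase gene P4ha1 at -1.06, whereas Vegfa was at 0.18. Of the pyruvate dehydrogenase kinases, which restrain entry of pyruvate into the TCA cycle, Pdk2 was at -1.27 (-1.52 to -1.03) and Pdk1 at -0.71 (-0.82 to -0.59), while Pdk3 was at -0.09 (-0.20 to 0.03). Pdk1 and Pdk2 were the only 2 of 34 TCA cycle and pyruvate entry genes to change in the authors' deposited table, both downward and also when adjusted over the list alone, and that list's median of -0.06 lay inside the random range (percentile 29.9).

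**Figure D2:**
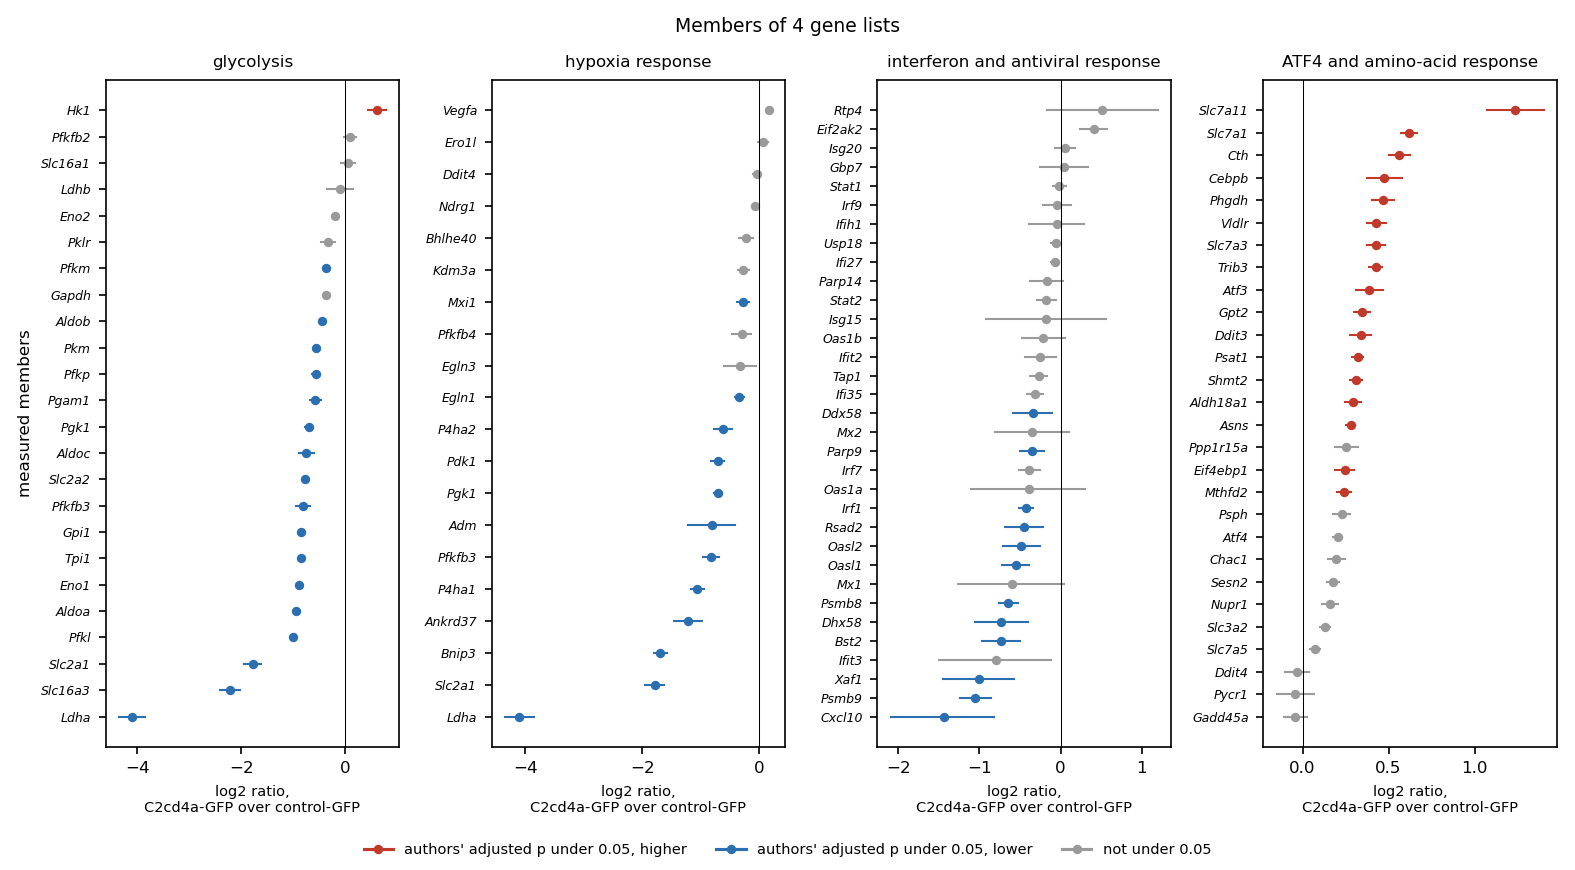
Points are the log2 ratios of C2cd4a-GFP over control-GFP for measured members of 4 gene lists (1 glycolysis gene is left out), with 95% counting intervals as lines, red and blue where the authors' deposited table has an adjusted p under 0.05 upward or downward and grey otherwise. Glycolysis, hypoxia and interferon genes lie mostly below 0 and ATF4 targets mostly above, with Ldha lowest at -4.10.

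The insulin gene Ins1 and several genes of glucose-stimulated secretion were lower in the C2cd4a-GFP library. The main insulin gene Ins2 differed little, and Pdx1, Mafa and some other beta-cell transcription factors were near equality. Ins1 had 52505 counts against 98394, a log2 ratio of -0.91 (-0.92 to -0.89), and the authors' deposited table has it falling by -0.67 (adjusted p = 0.0037). Ins2, by far the more abundant insulin gene, had 1747389 counts against 2002730, a log2 ratio of -0.20 (-0.20 to -0.20). It did not pass in the authors' deposited table, with -0.07 and an adjusted p of 0.824. Trpm5, a cation channel of beta cells, was at -1.25 (-1.39 to -1.11), and Sytl4, a granule-docking protein also known as granuphilin, at -0.69 (-0.75 to -0.64). Pdx1 (0.06, 0.02 to 0.10), Mafa (-0.05, -0.14 to 0.03), Nkx6-1 (-0.01, -0.09 to 0.07) and Foxo1 (-0.01, -0.13 to 0.11) all lay close to equality, whereas Neurod1 was at 0.37 (0.31 to 0.44) and rose in the authors' deposited table (0.42, adjusted p = 0.00175).

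By the authors' deposited table, 13 of 42 beta-cell function genes fell, 3 rose and 26 did not pass, against 14 falling and 5 rising when adjusted over the list alone. Besides those named above, Slc2a2, Npy, Ucn3, G6pc2 and Pcsk2 were among those that fell in the authors' deposited table, and Pam, Entpd3 and Papss2 rose. The list's median ratio in the pair was -0.14 and lay just inside the random range (-0.15 to 0.05, percentile 3.78). It fell outside that range when 10 expression bins were used (percentile 2.08) or when the mean of members was taken (percentile 0.59). For 27 beta-cell transcription factors the median was 0.00 (percentile 57.6), and the authors' deposited table has 5 rising and 1 falling, or 6 and 3 when adjusted over the list alone. Etv5, Bach2 (1.13, 0.89 to 1.37) and Etv1 were the higher members and Mnx1 the lower (-0.70, -0.88 to -0.53). The mean of this list stood above the random range (0.16, percentile 99.3), unlike its median. Exocytosis genes went both ways, with a median of -0.10 over 34 genes (percentile 7.88). Syt5 was at 0.84 (0.76 to 0.93), and 3 of these genes rose and 6 fell in the authors' deposited table, or 4 and 8 when adjusted over the list alone.

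Genes that beta cells normally repress showed no shared direction. The median of 23 such genes was 0.05 (percentile 70.3), and the authors' deposited table has 5 rising and 5 falling, the same numbers as when adjusted over the list alone. Cxcl12 (0.86, 0.62 to 1.09) and Lmo4 (0.64, 0.54 to 0.74) were higher, and Ldha and Parp3 (-0.63, -0.93 to -0.34) were lower. Of 9 dedifferentiation and progenitor markers, Cck rose in the authors' deposited table (0.72, adjusted p = 0.000139), as it did when adjusted over the list alone, and the median was 0.00 (percentile 58.3). Aldh1a3 had 0 counts in both libraries.

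Amino-acid response genes driven by ATF4 were higher and interferon response genes lower in the C2cd4a-GFP library. The ATF4 list had 25 of 28 measured genes with a ratio above 1 and a median log2 ratio of 0.29, above all random lists (-0.16 to 0.05). Slc7a11, the cystine-glutamate exchanger, was at 1.24 (1.07 to 1.40) and Slc7a1, a cationic amino-acid transporter, at 0.62 (0.57 to 0.67). Altogether 17 of the 28 rose and 0 fell in the authors' deposited table, including Trib3, Cth, Psat1, Phgdh and Asns, and 21 rose and 0 fell when adjusted over the list alone. The list of ER chaperones and the unfolded protein response did not move with it: its 30 genes had a median of -0.02 (percentile 65.8), with Calr at -0.35 (-0.37 to -0.33) and Hsp90b1 at -0.29 (-0.31 to -0.27). Of these, 1 rose and 5 fell in the authors' deposited table, or 2 and 6 when adjusted over the list alone.

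The interferon and antiviral list had a median of -0.34 over 33 genes, below all random lists (-0.15 to 0.15). Of the 33, 12 fell and 0 rose in the authors' deposited table, or 15 and 0 when adjusted over the list alone. Cxcl10, an interferon-induced chemokine, was at -1.44 (-2.09 to -0.81) and the immunoproteasome subunit gene Psmb9 at -1.05 (-1.24 to -0.86). NF-kappaB and inflammatory genes had a median of -0.11 over 15 genes (percentile 19.8), with Ptgs2 (1.05) and Lcn2 (0.77) higher. The authors' deposited table has 2 of these rising and 4 falling, Nfkbia among them, or 3 and 4 when adjusted over the list alone. With a minimum of 5 CPM this list's median was -0.38 and stood apart (percentile 0.16).

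Growth-factor and stress-linked genes moved in both directions. Among 29 immediate-early and CREB-responsive genes, Fosl1 (1.66, 1.12 to 2.21) and Dusp6 were the highest and Npas4 (-1.84, -2.10 to -1.58) and Jun (-0.96, -1.03 to -0.89) among the lowest. The authors' deposited table has 7 of them rising and 7 falling, or 8 and 10 when adjusted over the list alone. The list's median of -0.21 stood below the random range (percentile 0.20), but not with a minimum of 5 CPM (-0.10, percentile 7.33), with the mean of members (-0.10, percentile 6.33) or after the trend with exon length and GC content was removed (-0.04, percentile 29.3). Of 26 heat shock and oxidative stress genes 5 fell in the authors' deposited table, led by Hspa1a, Hspa1b and Hspb1, and 1 rose, Slc7a11, or 6 and 1 when adjusted over the list alone. That list's median was -0.21 (percentile 0.44), and -0.06 (percentile 14.2) once the trend was removed. For 25 p53 targets and cell death genes the median was 0.08 (percentile 91.8), with Gdf15 at 1.91 (1.40 to 2.46) and Mdm2, the negative regulator of p53, at 1.04 (0.99 to 1.09). The authors' deposited table has 6 of these rising and 2 falling, or 7 and 3 when adjusted over the list alone. This list stood above the random range with the mean of members (0.20, percentile 99.4) and without the trend (0.11, percentile 99.3).

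Cholesterol, fatty acid synthesis, cell cycle and FoxO lists had medians inside the random range, whereas fatty acid oxidation and PPAR targets stood lower. Cholesterol biosynthesis (median -0.05, percentile 25.3), with Idi1 at 0.60 (0.15 to 1.05) and Mvd at -0.72, had 3 of 25 genes rising and 1 falling in the authors' deposited table. Fatty acid synthesis (-0.03, percentile 45.8) had 2 of 22 rising, Acacb and Acsl4, and 1 falling, in the authors' deposited table. When adjusted over the list alone the authors' deposited table gives 3 and 1 for cholesterol and 3 and 2 for fatty acid synthesis. Agpat2 was at -0.60 (-1.08 to -0.13). Fatty acid oxidation and PPAR targets had a median of -0.22 (percentile 0.16), with 1 of 20 rising (Pparg) and 4 falling in the authors' deposited table, or 1 and 5 when adjusted over the list alone. This list no longer stood apart with the mean of members (percentile 3.83) or with no filter on low counts (percentile 2.57). Cell cycle genes (-0.06, percentile 37.9) had 3 of 39 rising, Ccnd2 among them, and 6 falling in the authors' deposited table, or 5 and 7 when adjusted over the list alone. Their median stood apart at -0.09 (percentile 0.96) without the trend. FoxO targets (0.06, percentile 80.6), with Tnfsf10 at 0.71 (0.20 to 1.23), had 1 of 21 rising and 3 falling in the authors' deposited table, or 2 and 4 when adjusted over the list alone.

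Ribosomal protein and oxidative phosphorylation transcripts were slightly lower in the C2cd4a-GFP library. All 77 cytosolic ribosomal protein genes had a ratio below 1, with a median of -0.28 (below all random lists), Rps4x at -0.30 (-0.32 to -0.28) and Rpl13a at -0.26 (-0.28 to -0.24). By the authors' deposited table, 4 of them fell, and 0 did when adjusted over the list alone. The 71 nuclear-encoded oxidative phosphorylation subunits had a median of -0.16 (percentile 0.03), with Atp5b at -0.15 and Atp5a1 at -0.14, whereas in the authors' deposited table their median was 0.00, with 1 falling and 0 when adjusted over the list alone. The ratio of the 2 libraries increased with exon length across genes (Spearman's rho 0.337) and decreased with GC content (-0.461). After both trends were removed together, the median was -0.07 for the ribosomal proteins (percentile 0.39) and 0.02 for the oxidative phosphorylation subunits (percentile 85.5). Of 13 mitochondrially encoded genes only 7 were measured, and COX2 and ATP6 were at 0 in both conditions of the authors' normalized values. These 7 were all higher, with a median of 0.31 (percentile 99.9), COX1 at 0.11 and CYTB at 0.31. Only ND2 rose in the authors' deposited table, as it did when adjusted over the list alone, and COX1 had a log2 fold change of -0.09 there without passing. Of 5 histone genes measured in these poly-A libraries the median was 0.45 (percentile 98.9), with Hist1h2bc at 0.92 (0.72 to 1.13), and 4 rose in the authors' deposited table, also when adjusted over the list alone.

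Markers of other cell types were mostly rare. Among 7 measured fibroblast markers Tagln had 62 counts against 21 and Col5a1 62 against 23, and 3 rose in the authors' deposited table, or 4 when adjusted over the list alone. Their median was 0.40 (percentile 95.9), and stood apart with the mean of members (0.53, percentile 98.6). The B-cell receptor gene Cd79a had 96 counts against 22 and rose in the authors' deposited table, as it did when adjusted over the list alone, within 5 leukocyte and endothelial markers of median 0.16 (percentile 75.5), where Cd74 was at -0.63 (-1.26 to 0.00). Of 7 acinar and ductal markers 1 rose and 1, Krt8, fell in the authors' deposited table, also when adjusted over the list alone, and the median was -0.10 (percentile 28.8). Other islet cell markers had a median of 0.25 over 10 genes (percentile 98.8), which fell back inside the random range with the mean of members (0.10, percentile 82.9). Gcg, which encodes glucagon, was at 0.60 (0.51 to 0.69), Ghsr at 0.76 (0.06 to 1.47), Gc at -0.71 (-0.76 to -0.66) and Rbp4 at -0.92 (-1.42 to -0.44). Among the 10, 2 rose and 1 fell in the authors' deposited table, or 3 and 1 when adjusted over the list alone. Among 25 commonly used reference genes 5 fell in the authors' deposited table, with Pgk1, Tfrc, Tubb5 and B2m among them, also when adjusted over the list alone, and the median was -0.10 (percentile 24.3). In all, 12 of the 29 lists stood apart from random lists, where 1.45 would if all genes varied independently. Genes of a list need not do so, and some lists share genes. The oxidative phosphorylation, immediate-early and heat shock lists came back inside the random range once the trend with exon length and GC content was removed. The excess is therefore no measure of chance.

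**Figure D3:**
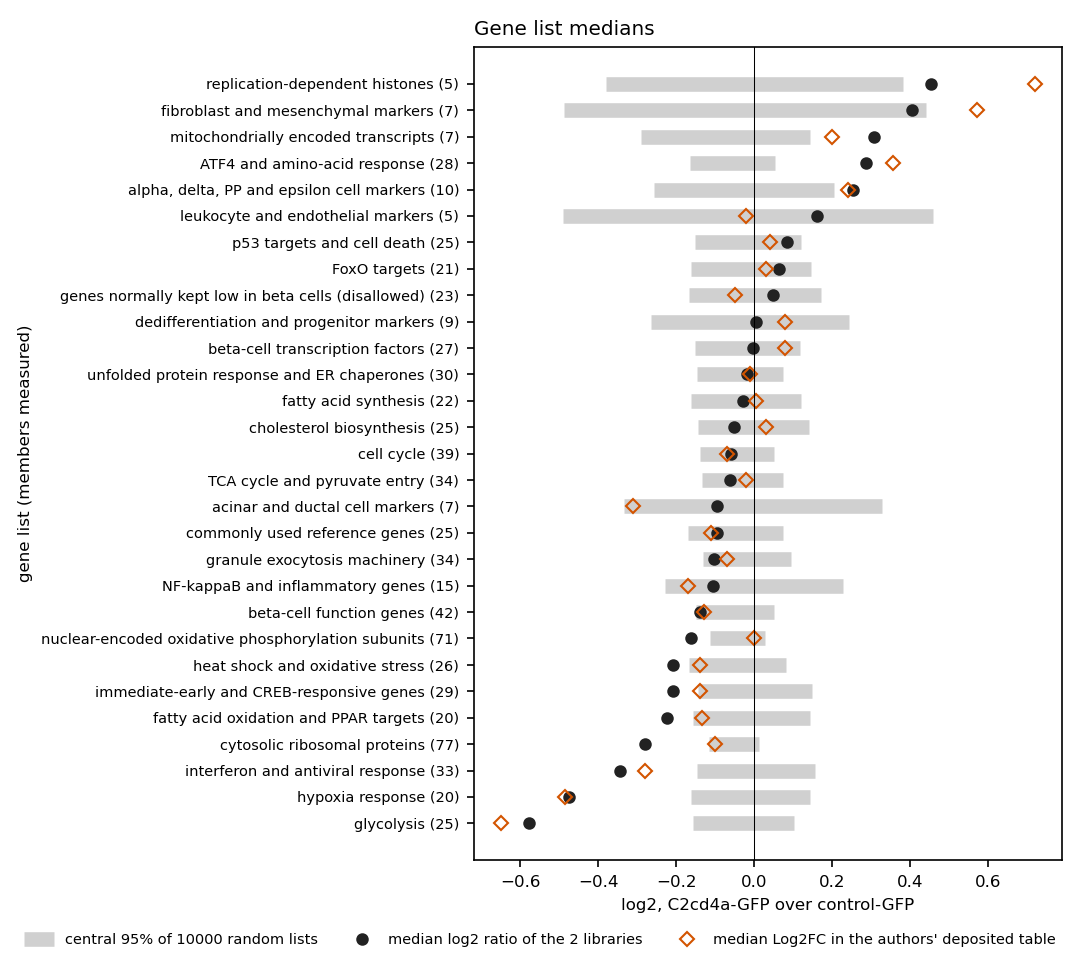
Black dots are the median log2 ratios of C2cd4a-GFP over control-GFP for 29 gene lists (measured members in brackets), grey bars the central 95% of 10000 random lists matched on expression, and open diamonds the medians of the log2 fold change in the authors' deposited table. Glycolysis (-0.58) and hypoxia (-0.47) lie lowest on both measures, and the oxidative phosphorylation subunits are at -0.16 in the pair and 0.00 in the authors' values.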

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

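The correction for exon length and GC content, the use of the authors' log2 fold change for lists, and the other adjusted p thresholds were chosen only after the data were seen. C2cd4a ranged from 8.51 to 8.57 (log2) over its 6 alternatives. Glycolysis, hypoxia, interferon and ATF4 lists kept their direction and stood apart under all 11 alternatives run on lists. DESeq2 size factors, total counts, upper quartile, thinning, a prior count of 2 and no filter left the 540 higher and 540 lower genes within 1.5 times. A minimum of 5 CPM gave 306 and 296, a ratio of 2 gave 116 and 88, a looser ratio gave 1769 and 1727, and an interval excluding the ratio of 1.5 itself gave 189 and 139, which follows from fewer or more genes qualifying. The exon length and GC correction left 350 lower genes. Beta-cell function genes stood apart with 10 bins (-0.14), the mean (-0.15), the correction (-0.092) and the authors' values (-0.13), and the cause was not tested. With the authors' values, 3 other lists that lay inside the random range in the pair also stood apart: acinar and ductal markers (-0.31, percentile 1.46, against -0.10 in the pair), fibroblast markers (0.57, percentile 99.5) and reference genes (-0.11, percentile 1.29), and the cause was not tested. Oxidative phosphorylation subunits turned from -0.16 to 0.015 under the correction, which removes the trends with exon length and GC content together, and to 0.00 with the authors' values. At an adjusted p of 0.01 the authors' deposited table has 558 rising and 524 falling genes. Pseudocounts of 0.5 and 5 on the authors' normalized values moved the 405 rising and 305 falling genes of at least 1.5-fold, counted with a pseudocount of 1 and without rounding among uniquely named genes, to no fewer than 394 and 301. Recomputed ratios of named genes stayed inside their counting interval in 388 cases and left it, without a change of sign, in 17 cases among highly counted genes. No paired analysis was possible because each group holds 1 library, and none could be left out.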

Other observations

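The tests for other cells in the control culture, with the choice to sum their markers both with and without keratins, the exon length and GC correction, the bootstrap interval of the HIF targets, the trend-corrected median of the 9 further ERK targets, the test on immediate-early genes and the choice of the ERK and HIF target sets came only after the results they follow up had been seen.

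A set of transcripts known as targets of ERK signalling stood out in the C2cd4a-GFP library. Etv4 had 98 counts against 17 (log2 ratio 2.53) and Spry4 171 against 59 (1.53), beside Etv5, Dusp6 and Fosl1. In the authors' deposited table all 5 of these rose, with log2 fold changes of 2.08 for Etv4 and 1.66 for Spry4. Among 9 further measured targets that had not been looked at, Epha2, which encodes an ephrin receptor, was at 1.35, Spred2 at 0.89, Dusp4 at 0.67 and Dusp5 at 0.53, and Phlda1 was at -0.03. The authors' deposited table has 5 of the 9 rising and 0 falling.

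Higher ERK pathway output is a candidate explanation for this group. The 9 targets not looked at before had a median log2 ratio of 0.53, above the central 95% of random lists (-0.28 to 0.29), as that explanation needs. They were chosen after the first 5 were seen to be high, and some share the Spry and Dusp families with them. Random lists of unrelated genes do not allow for genes that move together. The result therefore shows that related targets were higher together and does not test ERK activity itself. A trend of the ratio with exon length and GC content is argued against as the whole cause, since the median of these 9 was 0.77 after the trend was removed (random lists -0.23 to 0.22), and that of all 14, which include the 5 chosen for being high, was 0.91. Whether higher output reached immediate-early genes, many of which also answer to ERK, stays open: the 27 other listed immediate-early and CREB-responsive genes had a median of -0.24 (random lists -0.15 to 0.15), or -0.05 without the trend (-0.12 to 0.11), with Egr4 at -1.64, Fosb at -0.83, Junb at -0.76 and Egr1 at -0.41 but Fos at 0.09 and Myc at 0.68. With 1 culture per condition, an effect of C2cd4a and a difference between the cultures, in serum or timing for instance, both stay open.

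The lower glycolysis and hypoxia transcripts had a median of -0.57 over 41 genes, and the length and GC trend is argued against as the whole cause, because the median was -0.46 after its removal, below the random range of -0.09 to 0.06. Fibroblasts, leukocytes or endothelial cells in the control culture are argued against too, as their 41 listed markers differed by -2.68 CPM (control minus C2cd4a-GFP) where the Ldha gap alone was 77.6. For acinar or ductal cells in the control culture the summed test could not decide by its own rule. Their 32 markers differed by 85.5 CPM in the same sense, but Krt8 alone had 181 CPM in the control against 97.4. The 28 markers left without 4 keratins differed by -10.07 CPM. Those 28 argue against such cells as the source, and only the keratins leave them open. By the rule written before the test, the prediction of lower HIF activity was not met. The 16 HIF targets outside the lists had a median of -0.12, inside the random range of -0.19 to 0.19. Gys1, Fam162a and Kdm4b fell but Gbe1 and Plod2 rose in the authors' deposited table. A bootstrap interval added afterwards (-0.49 to 0.04) reached below the random range, so lower HIF activity was not excluded either. That interval treats the genes as independent. An effect of C2cd4a or a difference in density or oxygen between the cultures may also underlie the pattern, and neither was tested.

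The ratio of the 2 libraries increased with exon length across 12359 genes, which are not independent (Spearman's rho 0.337), and decreased with GC content (-0.461). The median log2 ratio went from -0.14 in the fifth of genes with a median length of 1162 bp to 0.16 in that of 6383 bp. An effect shared by the authors' condition values may hold part of this, as the log2 fold changes of the authors' deposited table also increased with length (rho 0.218), although those values may include these libraries. The C2cd4a-GFP library also departs from the authors' value for its condition along length (rho of raw over normalized 0.559), but so does the control library (0.527), and the spread of that log2 quotient was 0.181 and 0.111 (SD across genes). A difference in RNA quality or library preparation between this pair and whatever else entered the authors' values would be consistent with these numbers and stays open beside a biological effect on long transcripts.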
